A study of Mus musculus with 20 samples.

How the data were processed

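The series holds RNA-seq of AML-12 cells, an immortalised mouse hepatocyte line. There were 20 libraries in 4 groups of 5: wild-type and Ripk3-/- cells, each untreated or kept with 125 µM palmitate bound to bovine serum albumin for 24 h. Groups and replicate numbers were taken from the sample titles. None of the 4 groups is described as given albumin alone, so effects of palmitate and of its carrier cannot be told apart. The labels do not say that the 5 libraries of a group came from separate cultures, nor how many knockout clones were used, so p-values measure the spread between these libraries, which may be technical.

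Per the submitters' processing notes, reads were checked with FastQC 0.11.9 and the tools named were HISAT2, featureCounts 1.5.0-p3 and DESeq2, with the mouse build mm10. The versions of HISAT2 and DESeq2, the annotation and the strand setting are not given in the sources used here. The authors deposited 4 tables of genes, 1 per comparison of 2 groups. Per the file headers, each table gives the raw read count of every gene in the 10 libraries compared. It also gives the authors' normalised counts (a signal scaled between libraries, which equals the read count divided by 1 factor per library), FPKM, the log2 fold change, the p-value and the adjusted p-value of their test, and the gene length in bases. Each table lists only genes past the authors' adjusted p-value of 0.05, with no minimum fold. The number of genes the authors tested was worked out from their deposited p-values, since the Benjamini-Hochberg adjustment ties each adjusted value to its rank. It was 13764 for palmitate in wild-type cells, 12871 for palmitate in knockout cells, 16106 for genotype without palmitate and 17611 for genotype with palmitate. The authors also deposited 8 tables of GO and KEGG enrichment with a p-value and a number of genes per term, and these were only described.

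Library totals, computed from the deposited counts, FPKM and gene lengths, were 21.2 M to 30.1 M reads. The genes listed in a table held 15.8% to 47.9% of that total, depending on the table. For a gene as low as Ripk3 the 5 libraries of a group held 22 to 114 reads together. No 2 libraries of a group held identical values, and the chi-square of their counts divided by its degrees of freedom was at least 2.62 over 40 pairs, so every library was counted once. It was 34.92 to 47.92 in the 4 pairs with untreated knockout replicate 1 and at most 16.27 in all others, so this library stood apart in its group. There were 0 columns of other samples.

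The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust dispersions) on the deposited counts of the 10 libraries of a table, with the authors' size factors as effective library sizes and no replicate block. Its Benjamini-Hochberg adjustment used the number of genes the authors had tested. Because only passing genes are listed, these fits describe the listed genes and do not recount the genes of the transcriptome, and their dispersions were estimated from listed genes. Standard errors (SE) of log2 fold changes were taken from the F statistic. Groups were called separate when every library of one lay above every library of the other. The difference of the palmitate effects between genotypes was tested as an interaction term over all 20 libraries, on the 2993 genes with counts in all of them, with 1 joint set of size factors fitted to the deposited ones. Replicate numbers were tested as pairs, after the results were seen, by the mean correlation of libraries with the same number over 120 orders. In wild-type cells with and without palmitate it was 0.085 (exact permutation p = 0.00833, the smallest possible). The exact p was 0.0583 for palmitate in knockout cells, and 0.217 and 0.317 for genotype without and with palmitate, so some libraries may share a batch by number, and counts with a replicate block are given as an alternative. Ripk3 was also compared by a two-sided exact permutation test. Shared genes were set against the number that independent lists would share, using the smaller number of genes tested, and the comparisons set side by side share no libraries.

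There were 21 gene lists: necroptosis and death receptor signalling, apoptosis and p53 targets, fatty acid oxidation and PPAR alpha targets, lipid droplet and triglyceride turnover, fatty acid synthesis and desaturation, cholesterol synthesis and uptake, ER stress and integrated stress response, NF-kB and acute phase inflammation, interferon response, the nuclear and the mitochondrially encoded respiratory chain, mitochondrial biogenesis, dynamics and mitophagy, antioxidant and NRF2 targets, hepatocyte identity, cholangiocyte, mesenchymal and stellate, macrophage and leukocyte, and endothelial markers, cell cycle, glycolysis and hypoxia targets, and autophagy and lysosome. No gene stands in 2 lists. The split of a list into higher and lower genes was compared with that of the rest of the table by Fisher's exact test (two-sided), adjusted over lists and tables. Members of a list are regulated together, so these p-values treat as independent what may not be. The test asks about direction among listed genes, not whether a list holds more listed genes than others.

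The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Ripk3, the 8 largest rises and 8 largest falls per comparison among protein-coding genes with a mean normalised count of at least 100, an adjusted p under 0.05 and separate groups, and up to 3 members per list with the smallest adjusted p. The text names part of the genes this rule gave, and some of the others are not reported here. Genes named outside it are said to be so. Alternatives were DESeq2 1.42.0, limma 3.58.1 on log2 of the normalised count plus 0.1, 1 or 10, rescaling over the genes of a table, a minimum mean of 10, a replicate block, stricter thresholds and leaving out each library. Alternatives added after the data were examined were limma with a pseudocount of 1, FPKM totals as library sizes, leaving out chromosomes 9 and 14, keeping only genes of at least 1500 bases, and the lists without untreated knockout replicate 1, which tests little because the same listed genes were kept. The comparison of how many genes respond to palmitate in each genotype was moved, after a first look, to genes listed in both genotype tables, because most genes used first had been chosen on the knockout comparison. The design foresaw limma on normalised values or edgeR if the columns held raw counts, and they did.

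Gene length was the authors' deposited length. Transcript length and GC content came from the principal transcript of each gene in GENCODE M21, on the same mouse assembly. The edgeR step was tested on simulated data drawn from the real means and library sizes with 200 changed genes. At a fold of 1.5 it called 96% of the changed genes for palmitate in wild-type cells (2174 genes), 90% for palmitate in knockout cells (1316 genes), 78% for genotype without palmitate (2894 genes), 92% for genotype with palmitate (4333 genes) and 82% for the interaction (2993 genes). At a fold of 1.25 it called 74%, 74%, 46%, 68% and 56%, in the same order. Listed genes had a median fold of 1.15 to 1.20, below the smallest fold simulated. Changes of the size seen can be missed, but their share was not simulated. The simulated spread came from listed genes, so these shares may be too high. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.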

Results

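Gene expression was measured by RNA-seq in AML-12 cells, a mouse hepatocyte line, with or without Ripk3, a kinase that drives necroptosis. Wild-type and Ripk3-/- cells were left untreated or given 125 µM palmitate, a saturated fatty acid used to model lipid overload, for 24 h. Each of the 4 groups had 5 libraries of 21.2 M to 30.1 M reads. Levels below are the authors' normalised read counts as mean ± SD, n = 5 per group, log2 fold changes are edgeR estimates with their SE, and positions are on mm10.

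Ripk3 (ENSMUSG00000022221, chromosome 14, 55784995 to 55788865) was lower in every knockout library than in every wild-type library of the same treatment. Its normalised count was 4.66 ± 3.02 in untreated knockout cells and 18.03 ± 5.52 in untreated wild-type cells (n = 5 each, log2 fold change -1.90, SE 0.39, edgeR adjusted p = 0.00486). With palmitate it was 6.33 ± 3.91 against 21.5 ± 3.26 (log2 fold change -1.79, SE 0.32, edgeR adjusted p = 0.000209). A two-sided exact permutation test gave p = 0.00794 for each treatment, the smallest p that 5 against 5 libraries allow. Reads remained in the knockout libraries, 22 over the untreated and 29 over the palmitate libraries, against 97 and 114 in wild-type cells, so the counts are few and do not show whether a protein is made. With limma and a pseudocount of 10 the log2 fold change was -0.94 without palmitate and -0.98 with it, so its size depends on the method at such counts.

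**Figure D1:**
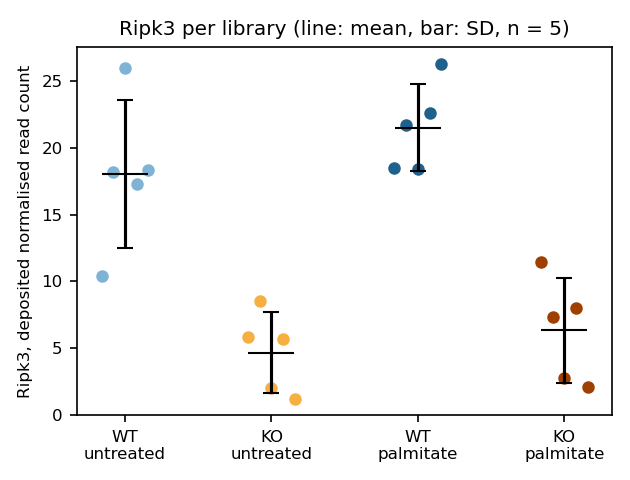
Ripk3 in each library (points) as deposited normalised read count, by genotype and treatment, with the mean (line) and SD (bar) of 5 libraries. Knockout libraries lay between 1.18 and 11.45, wild-type libraries between 10.42 and 26.28, and within each treatment the genotypes did not overlap.

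The comparison of palmitate with no treatment in wild-type cells asked how a hepatocyte line responds to a saturated fatty acid. Genes of the cell cycle, of lipid handling and of the integrated stress response were higher with albumin-bound palmitate than in untreated cells. No group given albumin alone is described, so the carrier could contribute to any palmitate difference below. Only 10 of 78 nuclear respiratory chain genes were listed, all lower. Among the genes that rose most were Slc7a11, the cystine importer (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), from 167 ± 23.2 to 823 ± 84.9 (log2 fold change 2.30, SE 0.09, edgeR adjusted p = 6.61e-11), and Mmp13, a collagenase, from 21.5 ± 12.1 to 210 ± 29.3 (3.26, SE 0.21, edgeR adjusted p = 1.09e-08, and 3.68 without untreated replicate 1, which was high). Ptgs2, the inducible cyclooxygenase, rose by 2.78 (SE 0.16) on the log2 scale, Fos, an immediate early transcription factor, by 2.25 (SE 0.17), and Sprr1a, a small proline-rich protein, by 3.03 (SE 0.17). The genes that fell most included the chemokine Ccl9 (-1.25, SE 0.07), endothelin Edn1 (-0.64, SE 0.07), and Ankrd1 (-0.63, SE 0.05), Vgll3 (-0.81, SE 0.09) and Csrp1 (-0.58, SE 0.03), which are linked to the cytoskeleton and the Hippo pathway.

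Of the 48 cell cycle genes, 43 were listed in the wild-type table, all higher (Fisher's exact test, adjusted p = 7.77e-10). Of these, edgeR called 42 over all genes tested and 43 adjusted over the list alone. The mitotic kinase Plk1 rose from 300 ± 47 to 778 ± 17.7 (log2 fold change 1.37, SE 0.08), Ccna2, a cyclin of S phase and mitosis, by 1.24 (SE 0.06) and Foxm1, a transcription factor of mitotic genes, by 1.08 (SE 0.05). Of the 42 genes of ER stress and the integrated stress response, 28 were listed higher and 2 lower (adjusted p = 0.000146). All 30 were called by edgeR over all genes tested and 30 adjusted over the list alone. They included Aldh1l2 of mitochondrial folate metabolism (1.97, SE 0.10) and the serine hydroxymethyltransferase Shmt2 (0.50, SE 0.04), both known targets of the transcription factor ATF4.

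Fatty acid oxidation and PPAR alpha targets had 19 members listed higher and 3 lower of 52 (adjusted p = 0.0253). All 22 were called by edgeR, over all genes tested or adjusted over the list alone. Without genes on chromosomes 9 and 14 the split was 17 and 3 (adjusted p = 0.0511). The mitochondrial carrier Ucp2 rose by 1.11 (SE 0.06) on the log2 scale. All 14 listed genes of fatty acid synthesis and desaturation were higher (adjusted p = 0.00385), and edgeR called 14 over all genes tested and also 14 adjusted over the list alone. Scd1, which makes monounsaturated fatty acids, rose from 1061 ± 117 to 2815 ± 98.6 (1.41, SE 0.06), and the desaturase Fads1 by 0.41 (SE 0.03). All 14 listed genes of cholesterol synthesis and uptake were higher (adjusted p = 0.00385), with 13 called over all genes tested and 14 adjusted over the list alone. Among them was Insig1, a sterol-regulated inhibitor of SREBP processing (0.26, SE 0.03). Of the lipid droplet list 5 were listed higher and 1 lower (adjusted p = 0.523), with 5 called over all genes tested and 5 adjusted over the list alone. The droplet coat protein Plin2 rose (0.42, SE 0.02).

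Of the 78 nuclear encoded respiratory chain genes only 10 were listed in wild-type cells with palmitate, where 15.79% of all genes tested were listed. All 10 were lower (median -0.14, Fisher's exact test, adjusted p = 0.00264). Of these, edgeR called 7 over all genes tested and 5 adjusted over the list alone, including the complex I subunit Ndufb7 (-0.19, SE 0.04). The other lists did not pass the direction test in this table. Antioxidant and NRF2 targets had 16 members listed higher and 3 lower (adjusted p = 0.0724), with 18 called over all genes tested and 19 adjusted over the list alone. They included the conjugate exporter Abcc2 (0.76, SE 0.05) and the glutathione transferase Gsta1 (4.21, SE 0.27), which is uncertain because its reads can fall on the near-identical Gsta2. NF-kB and acute phase genes went both ways, 11 listed higher and 14 lower (adjusted p = 0.519), with 22 called over all genes tested and 25 adjusted over the list alone. Here the alarmin Il33 rose by 0.66 (SE 0.07) and the adhesion molecule Vcam1 fell by 0.37 on the log2 scale (SE 0.04). The interferon list had 2 listed higher and 6 lower (adjusted p = 0.377), with 8 called over all genes tested and 8 adjusted over the list alone, although the antiviral gene Rsad2 rose from 1.73 ± 1.69 to 30.9 ± 7.13 (4.04, SE 0.39, and 4.80 without untreated replicate 2, which was high).

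The authors' deposited table listed 2174 of 13764 genes for palmitate in wild-type cells, 1220 higher and 954 lower, with 132 and 7 at an absolute log2 fold change of at least 1. From the same counts edgeR called 2016, 1156 higher and 860 lower, and 70.1% of the listed genes, all chosen for passing in this comparison, had groups that did not overlap. The share of called genes that were higher, 57.3%, was 42.0% after rescaling with DESeq2 size factors over the listed genes and 44.2% after TMM, which centre the listed genes by construction. In the authors' deposited table of KEGG terms, DNA replication had 24 genes higher and 0 lower (adjusted p = 6.44e-09) and Cell cycle had 50 and 6 (adjusted p = 4.03e-10).

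The same comparison in Ripk3-/- cells asked what palmitate does without the kinase. Cell cycle, lipid and integrated stress response genes rose again, led by Aldh1l2 (53 ± 5.68 to 205 ± 11.6, log2 fold change 1.95, SE 0.11, edgeR adjusted p = 7.04e-08), Slc7a11 (169 ± 27.1 to 533 ± 49.1, 1.67, SE 0.11, edgeR adjusted p = 4.06e-07) and Pdk4 (119 ± 24.7 to 337 ± 69.4, 1.49, SE 0.16), a kinase that shifts cells from glucose to fat oxidation. The largest falls were those of Gbp2, an interferon-induced GTPase (-0.94, SE 0.12), Ccl9 (-0.89, SE 0.11) and Vgll3 (-0.86, SE 0.11).

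In knockout cells 40 of the 48 cell cycle genes were listed, all higher (adjusted p = 2.38e-09). Of these, edgeR called 34 over all genes tested and 40 adjusted over the list alone. They included Cenpf, a kinetochore protein (406 ± 61.4 to 933 ± 72.4), and Cdc20, an activator of the anaphase-promoting complex (1.01, SE 0.09). The spindle genes Kif2c (102 ± 20.1 to 241 ± 29.5), Hmmr (1.21, SE 0.12) and Nusap1 (1.21, SE 0.09) were also among the largest rises. Fatty acid oxidation and PPAR alpha targets had 20 members listed higher and 1 lower (adjusted p = 0.00231), with 19 called over all genes tested and 21 adjusted over the list alone. Ucp2 rose by 1.06 (SE 0.07). All 11 listed fatty acid synthesis genes were higher (adjusted p = 0.0227), with 10 called over all genes tested and 11 adjusted over the list alone. Scd1 rose by 1.30 (SE 0.06) and Fads1 by 0.33 (SE 0.03). All 9 listed cholesterol genes were higher (adjusted p = 0.034), with 6 called over all genes tested and 9 adjusted over the list alone. Insig1 rose by 0.22 (SE 0.04). Of the lipid droplet list, 2 were listed higher and 1 lower (adjusted p = 1), and Plin2 rose by 0.41 (SE 0.03).

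ER stress and integrated stress response genes were listed 12 higher and 1 lower in knockout cells (adjusted p = 0.0413), with 9 called over all genes tested and 13 adjusted over the list alone. Among them was Cth, which makes cysteine from cystathionine (1.09, SE 0.10). All 7 listed mesenchymal and stellate markers fell (adjusted p = 0.0217), with 7 called over all genes tested and 7 adjusted over the list alone. Among them were N-cadherin Cdh2 (-0.17, SE 0.03), the basement membrane collagen Col4a1 (-0.19, SE 0.04) and Sparc, a matrix glycoprotein (-0.17, SE 0.03). The antioxidant list had 12 listed higher and 2 lower (adjusted p = 0.105), with 12 called over all genes tested and 14 adjusted over the list alone, including Abcc2 (0.61, SE 0.05) and, with the same uncertainty as above, Gsta1 (4.36, SE 0.41), which was 5.63 without untreated replicate 2. NF-kB and acute phase genes had 3 listed higher and 9 lower (adjusted p = 0.124), with 12 called over all genes tested and 12 adjusted over the list alone. The macrophage growth factor Csf1 fell by 0.28 on the log2 scale (SE 0.03) and Nfkb1, an NF-kB subunit, by 0.23 (SE 0.03), whereas Ptgs2 rose by 1.87 (SE 0.20). The hepatocyte gene Alb rose in knockout cells (0.78, SE 0.11) and in wild-type cells (0.80, SE 0.07). No nuclear respiratory chain gene was listed in this table, which does not show that palmitate acts on them differently by genotype.

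The authors' deposited table listed 1316 of 12871 genes for palmitate in knockout cells, 742 higher and 574 lower, with 77 and 5 at an absolute log2 fold change of at least 1. From the same counts edgeR called 973, 567 higher and 406 lower, and 66.1% of the listed genes had groups that did not overlap. The share of called genes that were higher, 58.3%, was 38.0% after rescaling with DESeq2 size factors over the listed genes and 43.8% after TMM. Of the 19 listed genes of up to 600 bases 84.2% were higher, against 53% of genes longer than 2500 bases. In wild-type cells these shares were 42.1%, also of 19 genes, and 56.8%. Untreated knockout replicate 1, low for short genes as described below, is part of the knockout comparison, and its part in this was not tested. In the authors' deposited table of KEGG terms, PPAR signaling pathway had 20 genes higher and 0 lower (adjusted p = 0.000971) and Regulation of actin cytoskeleton had 7 and 29 (adjusted p = 0.000313).

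Genes listed for palmitate in both genotypes moved in the same direction. The wild-type and knockout tables shared 984 genes, 45.3% of the wild-type and 74.8% of the knockout genes, 602 higher in both and 382 lower in both, with 0 in opposite directions, where independent lists would share 70.3 higher and 42.5 lower. Across these genes, which are not independent replicates and were chosen for passing in both tables, the log2 fold changes had a Pearson r of 0.974, and over all 2993 genes with counts in every library it was 0.863. Over the 984 genes the slope of knockout on wild-type was 0.859, and that of wild-type on knockout 1.105. The median absolute log2 fold change was 0.29 in wild-type and 0.265 in knockout cells, and 637 of the 984 had the smaller change in knockout cells. The interaction of genotype and palmitate, the test of a difference itself, called 0 of 2993 genes with edgeR, where 172 had an unadjusted p under 0.05. DESeq2 called 6 genes and limma 0, with 179 and 171 at an unadjusted p under 0.05. The 6 genes, named after their values were seen, were Slc7a11 (difference of knockout from wild-type on the log2 scale -0.64, SE 0.15, DESeq2 adjusted p = 0.0186), Slc20a1, Pim2 and Gm26917 with smaller rises in knockout cells, and Ubb and Aldh1a7, whose palmitate log2 fold change was 0.17 and 0.35 in knockout cells and -0.05 and 0.01 in wild-type cells. The replicate block in edgeR called 4 genes, Ubb, Aldh1a7, Gm26917 and Dusp4, a MAP kinase phosphatase with a smaller rise in knockout cells (difference -0.53, SE 0.09, edgeR adjusted p = 0.0157). The genes in this test were listed for palmitate in both genotypes or for genotype in both treatments, since only those had counts in all 20 libraries. A gene listed for palmitate in 1 genotype alone, and for genotype only with palmitate, could not enter it. The test therefore left out genes for which a difference would be likely, and its count covers only the genes tested.

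**Figure D2:**
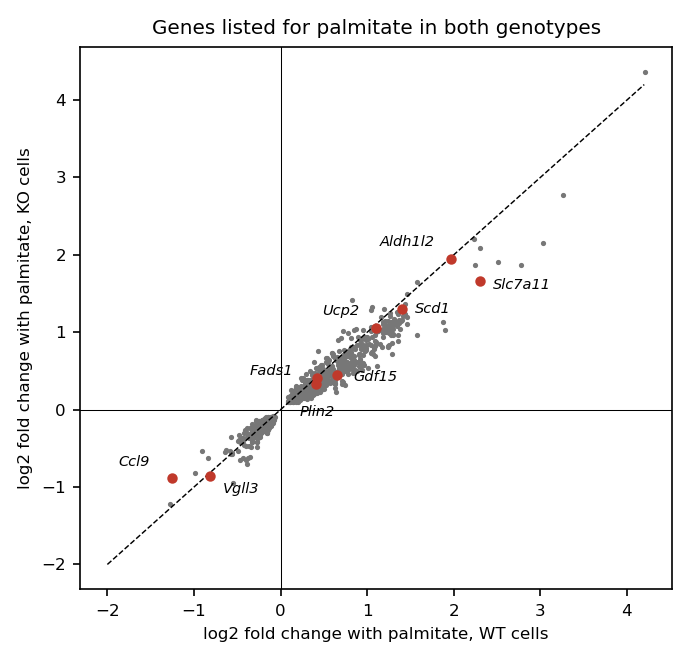
Log2 fold change with palmitate in wild-type cells (horizontal) and knockout cells (vertical) for the 984 genes listed in both tables, with the dashed line at equal change and 9 named genes in red. All 984 had the same sign in both genotypes, and Slc7a11 lay at 2.30 in wild-type and 1.67 in knockout cells.

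The comparison of knockout with wild-type cells without palmitate asked what the loss of Ripk3 goes with at rest. Knockout cells had lower levels of the hepatocyte genes Apoe, Ambp and Apoh. Their list, hepatocyte identity, had 5 listed higher and 11 lower and did not pass the direction test (Fisher's exact test, adjusted p = 0.37). Listed genes of fatty acid synthesis and of the respiratory chain were mostly higher. The fatty acid synthesis list did not pass the direction test without genes on chromosomes 9 and 14. The respiratory chain shift was not seen in every knockout library, and other short genes moved with it. It therefore does not separate a genotype difference from a library effect. Apoe, the apolipoprotein of remnant particles (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), was 314 ± 41.8 in knockout and 2270 ± 219 in wild-type cells (log2 fold change -2.86, SE 0.09, edgeR adjusted p = 4.34e-10). The largest falls also included Mal2, which sorts proteins to the apical membrane (18.2 ± 8.87 against 244 ± 14.9, -3.75, SE 0.19), the heparan sulfate proteoglycan Gpc4 (36.7 ± 9.81 against 420 ± 25.8, -3.50, SE 0.13), the guanine deaminase Gda (-1.80, SE 0.10), the adenylyl cyclase Adcy8 (-1.80, SE 0.13) and vitronectin, Vtn (-1.59, SE 0.12). Among the largest rises were Slc16a7, a monocarboxylate transporter (36.8 ± 4 to 164 ± 9.33, 2.15, SE 0.11, edgeR adjusted p = 2.1e-08), the sodium pump subunit Atp1b1 (1.93, SE 0.14), the cadherin Cdh16 (1.65, SE 0.08), the interferon-induced Ifi27 (1.83, SE 0.13) and Nos2, the inducible nitric oxide synthase (1.16, SE 0.11).

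Of the 78 nuclear respiratory chain genes, 39 were listed higher and 1 lower in untreated knockout cells (median 0.28, adjusted p = 1.73e-09). Of these, edgeR called 31 over all genes tested and 40 adjusted over the list alone. They included the complex I subunits Ndufa11 (0.34, SE 0.06) and Ndufa5 (0.54, SE 0.11) and cytochrome c, Cycs (0.28, SE 0.06). Among genes with a deposited length of at least 1500 bases, which may still have short transcripts, the list had 14 higher and 1 lower (adjusted p = 0.00322). Short genes of other kinds were higher too, and both moved with the library. Over the 176 listed genes of up to 600 bases, 82.4% were higher in knockout cells. The median of these short genes, relative to the wild-type mean, was 0.56 to 0.79 in knockout replicates 2 to 5 and 0.01 in knockout replicate 1. The respiratory chain median was 0.27 to 0.43 in replicates 2 to 5 and 0.02 in replicate 1, inside the range of the wild-type libraries, -0.12 to 0.12. The mitochondrial list had 1 listed gene, mt-Nd3 (1.01, SE 0.28, adjusted p = 0.0297), which is uncertain because it shares reads with nuclear copies. Its call was lost without any of 8 of the 10 libraries, with adjusted p from 0.0521 to 0.0841.

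**Figure D3:**
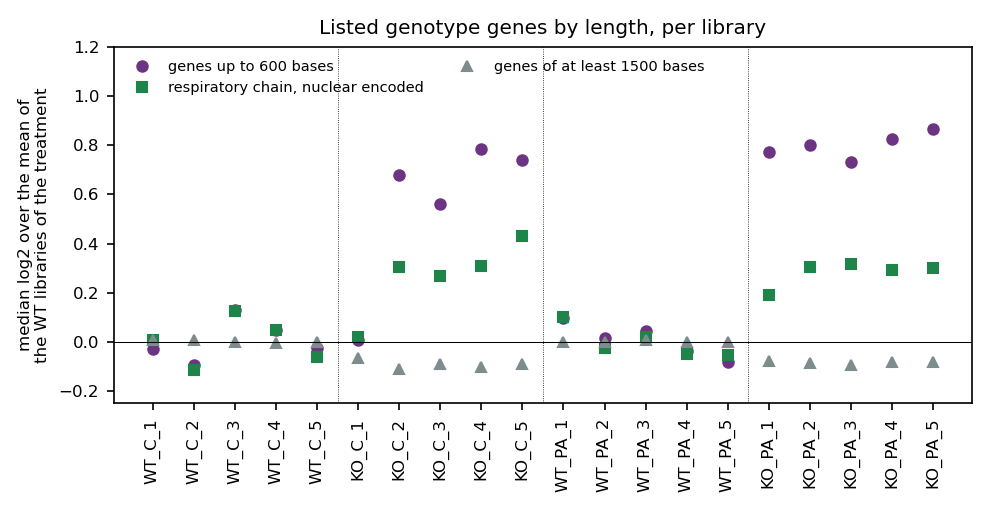
Median log2 level, relative to the mean of the wild-type libraries of the same treatment, of listed genes of up to 600 bases (circles), nuclear respiratory chain genes (squares) and listed genes of at least 1500 bases (triangles) in each of 20 libraries. Untreated knockout replicate 1 lay at 0.01 for short genes, whereas the other knockout libraries lay between 0.56 and 0.87.

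Fatty acid synthesis genes were listed 11 higher and 1 lower in untreated knockout cells (adjusted p = 0.034), with 12 called over all genes tested and 12 adjusted over the list alone. Without genes on chromosomes 9 and 14 the split was 10 and 1 (adjusted p = 0.119), against a higher share of higher genes in the rest of the table. Scd1 rose from 1016 ± 113 to 1812 ± 165 (0.84, SE 0.08) and the elongase Elovl6 by 0.32 (SE 0.05). All 4 listed cholesterol genes were higher (adjusted p = 0.361), with 3 called over all genes tested and 2 adjusted over the list alone. Fatty acid oxidation genes went both ways, 6 listed higher and 8 lower (adjusted p = 0.871), with 13 called over all genes tested and 14 adjusted over the list alone. Of the lipid droplet list 3 were listed higher and 6 lower (adjusted p = 0.667), with the liver droplet protein Hsd17b13 lower (-0.65, SE 0.10). All 7 listed autophagy and lysosome genes were lower (adjusted p = 0.034), with 6 called over all genes tested and 6 adjusted over the list alone. Cathepsin B, Ctsb (-0.25, SE 0.04), and Gabarapl1, which acts in autophagosome formation (-0.20, SE 0.04), were among them. Ctsb lies on chromosome 14, and without chromosomes 9 and 14 all 5 remaining genes were lower (adjusted p = 0.0557), as were all 6 of at least 1500 bases (adjusted p = 0.119).

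Hepatocyte identity genes were listed 5 higher and 11 lower (adjusted p = 0.37), with 14 called over all genes tested and 16 adjusted over the list alone. Those lower included Apoe, the protease inhibitor precursor Ambp (-0.68, SE 0.04) and Apoh, an apolipoprotein (-1.65, SE 0.16), and the glucose transporter Slc2a2 of the glycolysis list was also lower (-0.76, SE 0.06). Cholangiocyte markers were listed 4 higher and 2 lower (adjusted p = 0.928), with 5 called over all genes tested and 6 adjusted over the list alone. Krt19, a biliary keratin (0.41, SE 0.06), osteopontin, Spp1 (0.33, SE 0.05), and the water channel Aqp1 (1.48, SE 0.11) were higher. Among mesenchymal markers, 4 were listed higher and 3 lower (adjusted p = 1), with fibronectin, Fn1 (-0.52, SE 0.06), and Tgfb3 (-0.56, SE 0.05) lower and the collagen Col6a1 higher (1.43, SE 0.15). The death receptors Fas (-0.53, SE 0.06) and Tnfrsf1a (-0.28, SE 0.03) were lower, in a necroptosis and death receptor list with 3 listed higher and 5 lower (adjusted p = 0.776), of which 6 were called over all genes tested and 8 adjusted over the list alone.

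The authors' deposited table listed 2894 of 16106 genes for genotype without palmitate, 1464 higher and 1430 lower, with 168 and 143 at an absolute log2 fold change of at least 1. From the same counts edgeR called 2336, 1141 higher and 1195 lower, and 57% of the listed genes had groups that did not overlap. The share of called genes that were higher, 48.8%, was 59.2% after TMM over the listed genes. In the authors' deposited table of KEGG terms, Oxidative phosphorylation had 57 genes higher and 4 lower (adjusted p = 0.000959) and Metabolism of xenobiotics by cytochrome P450 had 6 and 20 (adjusted p = 0.0239).

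With palmitate, the comparison of knockout with wild-type cells asked how the genotypes differ under lipid load. Most of the genotype differences seen at rest were found again, and listed genes of ER stress and the integrated stress response were mostly lower in knockout cells. Apoe was 355 ± 29.5 against 2147 ± 128 (log2 fold change -2.60, SE 0.05, edgeR adjusted p = 1.5e-18), Gpc4 26.4 ± 4.27 against 382 ± 27.8 (-3.85, SE 0.11), Mal2 14.4 ± 5.07 against 260 ± 17.4 (-4.15, SE 0.14), Gda -1.81 (SE 0.08) and Vtn -1.42 (SE 0.14). Axin2, a feedback inhibitor and target of Wnt signalling (-1.70, SE 0.11), and the actin-binding Dbn1 (-1.39, SE 0.11) were also among the largest falls. Cdh16 (426 ± 44.2 to 1391 ± 129, 1.70, SE 0.07), Atp1b1 (1.99, SE 0.11), Aqp1 (1.57, SE 0.10) and the extracellular superoxide dismutase Sod3 (1.59, SE 0.11) were higher. Of the 2894 and 4333 genes listed for genotype without and with palmitate, 2239 were shared, 1114 higher in both, 1123 lower in both and 2 opposite, where independent lists would share 197.4 higher and 191.9 lower.

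ER stress and integrated stress response genes were listed 1 higher and 15 lower (adjusted p = 0.00264), with 13 called over all genes tested and 14 adjusted over the list alone. They included the asparaginyl-tRNA synthetase Nars (-0.23, SE 0.03) and the ER chaperones Dnajc3 (-0.24, SE 0.03) and Calr (-0.19, SE 0.03). Without palmitate this list had 3 listed higher and 5 lower (adjusted p = 0.776), with 7 called over all genes tested and 7 adjusted over the list alone, and the difference between treatments was not tested for the list. NF-kB and acute phase genes were listed 4 higher and 13 lower (adjusted p = 0.105), with 17 called over all genes tested and 17 adjusted over the list alone. Those lower included the serum amyloid genes Saa1 (-1.40, SE 0.16) and Saa2 (-1.17, SE 0.16), which can share reads. Fatty acid synthesis genes were listed 10 higher and 1 lower (adjusted p = 0.0495), with 11 called over all genes tested and 11 adjusted over the list alone. Scd1 (0.73, SE 0.05) and Fasn, the fatty acid synthase (0.21, SE 0.02), were higher, and without genes on chromosomes 9 and 14 the split was 9 and 1 (adjusted p = 0.174). Cholesterol genes were listed 9 higher and 1 lower (adjusted p = 0.0823), with 10 called over all genes tested and 10 adjusted over the list alone. Fatty acid oxidation genes were listed 16 higher and 10 lower (adjusted p = 0.659), with 25 called over all genes tested and 26 adjusted over the list alone. The electron transfer flavoprotein Etfb was higher (1.12, SE 0.10) and the pantetheinase Vnn1 lower (-0.65, SE 0.05).

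Of the 78 nuclear respiratory chain genes, 60 were listed higher and 2 lower (median 0.29, adjusted p = 4.71e-14). All 62 were called by edgeR over all genes tested and 62 adjusted over the list alone. They included the complex IV subunits Cox7c (2342 ± 96.2 to 4011 ± 166, 0.78, SE 0.03), Cox6c (0.40, SE 0.03) and Cox7b (0.37, SE 0.03). Among genes of at least 1500 bases 30 were higher and 2 lower (adjusted p = 6.11e-08). Here too short genes were higher in knockout libraries, 87.2% of the 273 listed genes of up to 600 bases, with medians of 0.73 to 0.87 per library. The ATP synthase subunit Atp5k (1.81, SE 0.13) and the ribosomal protein Rps29 (1.60, SE 0.13) have near-identical copies, so their values are uncertain. The mitochondrially encoded list had 5 listed higher and 2 lower (adjusted p = 0.776), with 7 called over all genes tested and 7 adjusted over the list alone. Its most abundant named member, mt-Co1, was lower (334903 ± 9381 to 304931 ± 14222, -0.14, SE 0.03), while mt-Nd3 (1.70, SE 0.14) and mt-Co3 (0.75, SE 0.13), which share reads with nuclear copies, were higher.

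Autophagy and lysosome genes were listed 4 higher and 16 lower with palmitate (adjusted p = 0.034), with 18 called over all genes tested and 20 adjusted over the list alone. Ctsb (-0.22, SE 0.02) and cathepsin Z, Ctsz (-0.21, SE 0.03), were lower, and among genes of at least 1500 bases the split was 4 and 15 (adjusted p = 0.18). Hepatocyte genes were listed 9 higher and 12 lower (adjusted p = 0.782), with 21 called over all genes tested and 21 adjusted over the list alone, with Ambp (-0.58, SE 0.03) and the transferrin receptor Tfr2 (-0.57, SE 0.04) lower. Krt19 of the cholangiocyte list was higher (0.48, SE 0.03), and Fn1 (-0.56, SE 0.04) and the receptor Tgfbr2 (-0.36, SE 0.03) of the mesenchymal list were lower. That list had 5 listed higher and 11 lower (adjusted p = 0.37), with 16 called over all genes tested and 16 adjusted over the list alone. Fas (-0.51, SE 0.05) and Tnfrsf1a (-0.25, SE 0.03) were lower again. The necroptosis and death receptor list had 2 listed higher and 5 lower (adjusted p = 0.597), with 7 called over all genes tested and 7 adjusted over the list alone.

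The lists of apoptosis, interferon, glycolysis, mitochondrial biogenesis, and cholangiocyte, macrophage and endothelial markers passed the direction test in none of the 4 tables. With palmitate, knockout against wild-type, apoptosis and p53 targets had 6 listed higher and 5 lower (adjusted p = 1, 11 called over all genes tested and 11 adjusted over the list alone), interferon response 6 and 6 (adjusted p = 1, 12 and 12), glycolysis and hypoxia targets 10 and 8 (adjusted p = 1, 17 and 18), and mitochondrial biogenesis, dynamics and mitophagy 4 and 3 (adjusted p = 1, 7 and 7). In the same table cholangiocyte markers had 6 listed higher and 3 lower (adjusted p = 0.776, 8 and 9), macrophage and leukocyte markers 1 and 0 (adjusted p = 1, 1 and 1), and endothelial markers 1 and 2 (adjusted p = 0.887, 3 and 3). In the palmitate comparison of wild-type cells, p53 targets had 6 listed higher and 4 lower (adjusted p = 1), including the stress cytokine Gdf15 (0.65, SE 0.05), which also rose in knockout cells (0.45, SE 0.07). Glycolysis genes had 11 and 2 there (adjusted p = 0.15), including the pyruvate kinase Pkm (0.40, SE 0.03), and hepatocyte genes 5 and 4 (adjusted p = 1), with transthyretin, Ttr, lower (-0.21, SE 0.04).

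**Figure D4:**
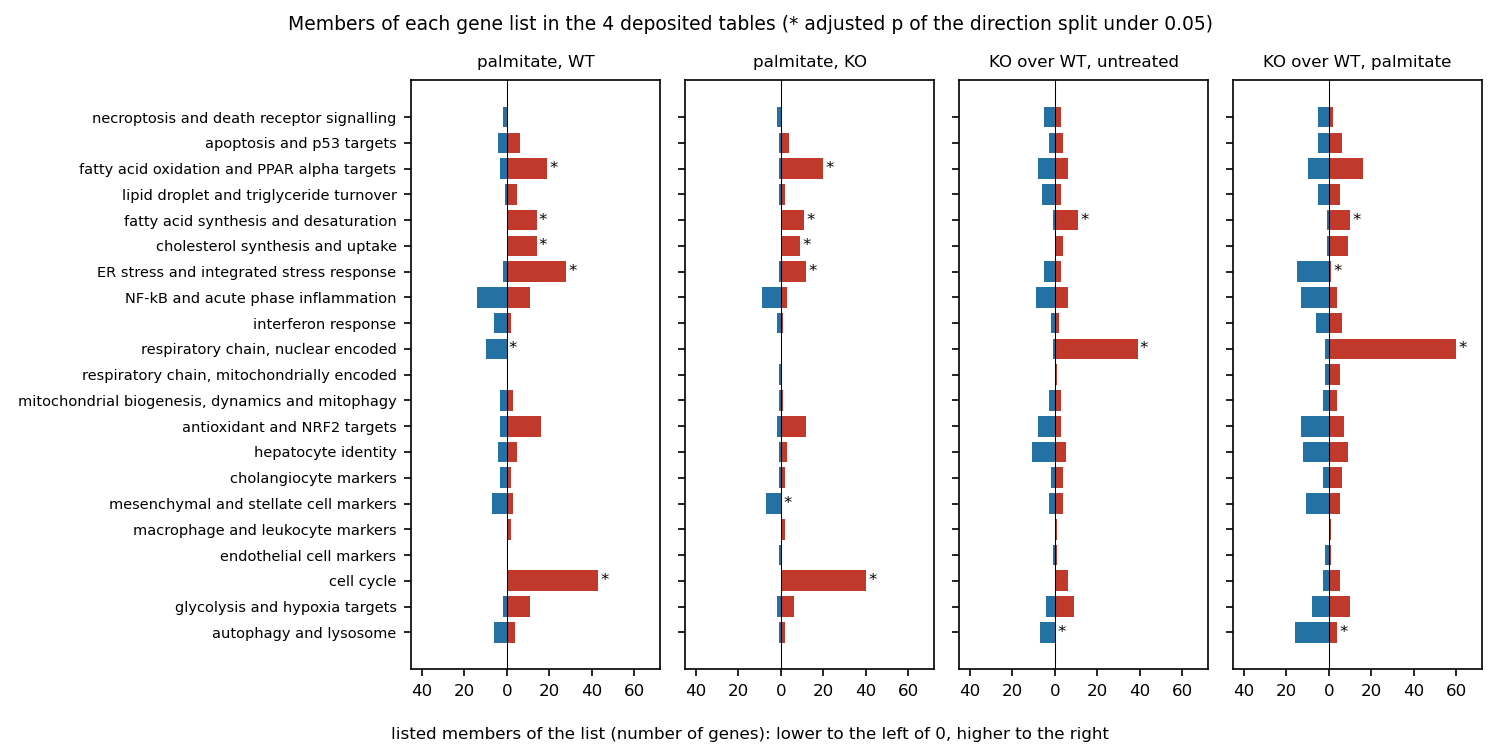
Number of members of each of 21 gene lists in the 4 deposited tables, lower to the left and higher to the right of 0, with an asterisk where the direction split passed Fisher's exact test. Cell cycle had 43 higher in wild-type and 40 in knockout cells with palmitate, and the nuclear respiratory chain had 39 and 60 higher in knockout than in wild-type cells without and with palmitate.

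The authors' deposited table listed 4333 of 17611 genes for genotype with palmitate, 2172 higher and 2161 lower, with 268 and 201 at an absolute log2 fold change of at least 1. From the same counts edgeR called 4259, 2131 higher and 2128 lower, and 70.5% of the listed genes had groups that did not overlap. In the authors' deposited table of KEGG terms, Oxidative phosphorylation had 88 genes higher and 9 lower (adjusted p = 2.41e-09). Genes lower in knockout cells were unevenly spread over the genome. On chromosome 14, where Ripk3 lies, 202 of 218 listed genes were lower without palmitate and 238 of 270 with it. On chromosome 9 it was 217 of 251 and 291 of 351. The share lower on both chromosomes together was 89.3% against 41.7% elsewhere without palmitate and 85.2% against 44% with palmitate, for chromosomes chosen after these shares were seen. For palmitate itself these shares were 40.1% against 44.3% in wild-type cells. In the genotype comparisons chromosomes 2, 6 and 10, counted as elsewhere here, also had more listed genes lower than higher. Their shares lower were 55.1% to 61.3% without palmitate and 55.8% to 63.5% with it.

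**Figure D5:**
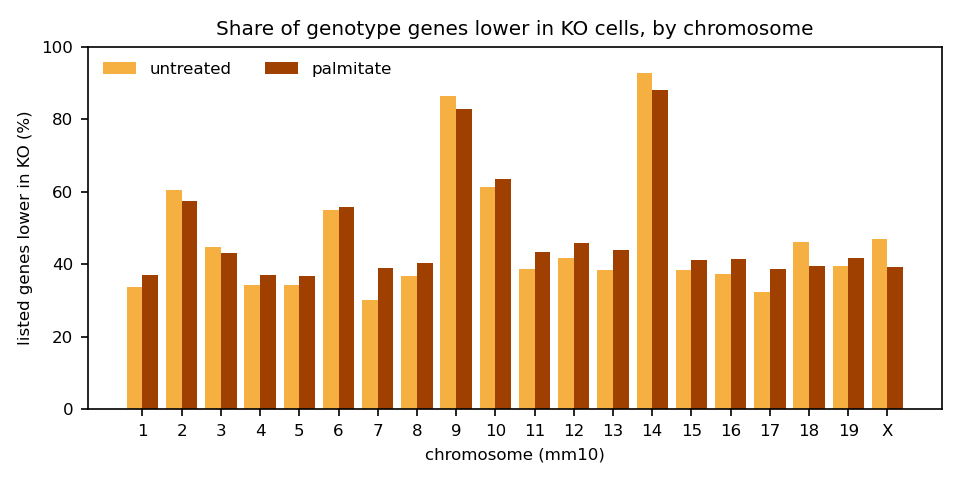
Percent of the genes listed for genotype that were lower in knockout cells, by chromosome, without palmitate (light) and with palmitate (dark). Chromosomes 14 (92.7% and 88.1%) and 9 (86.5% and 82.9%) had the highest shares.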

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

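Dixon's ratio was computed within each group of 5 libraries for the named genes, as fixed beforehand, and no test in this part was chosen after a result was seen. It marked 17 of 254 groups, where chance marks about 1 in 20 groups, or 12.7. Every marked library was kept in the tests.

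In the comparison of palmitate in wild-type cells, 2 untreated libraries stood high, replicate 1 for Mmp13 (42.5, others 12.6 to 20.2) and replicate 2 for the interferon gene Rsad2 (4.74, others 0.904 to 1.01). Palmitate replicate 2 was high for Slc7a11 (968, others 743 to 806) and low for Edn1 (216, others 243 to 254). Palmitate replicate 5 was low for Ndufb7 (1192, others 1224 to 1236), and palmitate replicate 1 was high for Pkm (34755, others 33001 to 33420).

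In the comparison of palmitate in knockout cells, untreated replicate 2 was high for Gsta1 (12.7, others 0.935 to 2.68), and palmitate replicate 2 was high for Ucp2 (830, others 666 to 711).

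In the comparison of genotypes without palmitate, knockout replicate 4 was high for Elovl6 (2409, others 2045 to 2119). Knockout replicate 5 was high for Krt19 (9327, others 7651 to 8062) and low for Fn1 (21661, others 25760 to 27195), and wild-type replicate 2 was high for Gda (497, others 399 to 425).

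In the comparison of genotypes with palmitate, knockout replicate 1 was low for Atp5k (1069, others 1386 to 1505) and Cox6c (3757, others 4082 to 4131). Wild-type replicate 1 was high for Cox6c (3278, others 2975 to 3022), replicate 2 low for Atp1b1 (58.4, others 80 to 86.1) and replicate 5 high for Nars (12217, others 11259 to 11414). Over all comparisons, wild-type palmitate replicate 2 was marked most often, 3 times.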

How the results depend on the processing

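The alternatives leaving out chromosomes 9 and 14, keeping genes of at least 1500 bases, limma with a pseudocount of 1, FPKM totals as library sizes and the test of replicate numbers were chosen only after the results were seen. Requiring an absolute log2 fold change of at least 1 left 137 genes for palmitate in wild-type cells (130 higher, 7 lower), 80 in knockout cells (75 and 5), 295 for genotype without palmitate (156 and 139) and 462 with palmitate (263 and 199). It left 70 palmitate genes and 216 genotype genes shared, and 0 gene lists. Nearly all palmitate genes left were higher, so a test of direction could hardly pass for them. Cell cycle still had 19 higher and 0 lower in wild-type cells and 15 and 0 in knockout cells. For genotype the nuclear respiratory chain kept 1 gene without palmitate and 2 with it, too few to test. The count of 0 lists therefore does not speak against the list results. An adjusted p under 0.01 left 1194, 498 and 1066 genes in the first 3 comparisons and 1468 shared genotype genes. The interaction, 0 in edgeR, was 6 with DESeq2, 4 with the replicate block, 2 without untreated knockout replicate 1 and 0 without untreated wild-type replicate 1. Leaving out each library gave 1551 to 1814, 675 to 1058, 1620 to 2392 and 3763 to 3947 genes, and the replicate block 2085, 919, 2038 and 3963. DESeq2 called 2151, 1225, 2730 and 4300 genes. Gene lists passed 19 times in the main setting, 16 without chromosomes 9 and 14 and 20 with genes of at least 1500 bases. The cholesterol list for genotype with palmitate passed in these last 2 settings only (Fisher's exact test, adjusted p = 0.037 and 0.0292). Antioxidant targets for palmitate in wild-type cells (0.0257) and cell cycle for genotype without palmitate (6 higher, 0.0356) passed only with genes of at least 1500 bases. Of the 125 named values, 0 were reversed with a pseudocount of 10, with the block or with any library left out, and mt-Nd3 for genotype without palmitate was lost when single libraries were left out and with a pseudocount of 10 (adjusted p = 0.0591).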

Other observations

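The gene families, the copy number test, the count of knockout libraries above the wild-type range, the tests of the number of palmitate genes and the split of the interaction were chosen only after the results were seen. Knockout cells had lower levels of conjugating enzymes, some of which are in the antioxidant list. Of the glutathione, glucuronosyl and sulfotransferases, 3 were listed higher and 16 lower without palmitate (Fisher's exact test, adjusted p = 0.00709, 17 called by edgeR) and 5 and 16 with it (adjusted p = 0.0451, 21 called). The theta class transferases Gstt2 (-2.14, SE 0.27) and Gstt3 (-1.42, SE 0.13), and Gstm1, an abundant mu class enzyme (-0.34, SE 0.05), were lower without palmitate. Ugt2b34, a glucuronosyltransferase with close paralogs (-1.06, SE 0.09), was lower too. The sulfotransferases Sult1c2 (0.36, SE 0.04) and Sult1d1 (0.55, SE 0.08) were higher. Of Wnt targets, Axin2 (-1.74, SE 0.12) and the receptor-degrading ligase Rnf43 (-0.57, SE 0.04) were lower without palmitate, while the related Znrf3 was higher (0.24, SE 0.05), and the family did not pass (adjusted p = 0.501).

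DNA replication factors were higher with palmitate. In wild-type cells 22 were listed higher and 0 lower (Fisher's exact test, adjusted p = 2.29e-05, 22 called), and in knockout cells 16 and 0 (adjusted p = 0.000576, 13 called). The helicase subunits Mcm3 (0.66, SE 0.05) and Mcm5 (0.78, SE 0.09) and the loading factor Cdc6 (0.83, SE 0.12) rose in wild-type cells. Immediate early genes were listed 7 higher and 1 lower there (adjusted p = 0.158, 8 called), with Fosb, a partner of Jun proteins (2.30, SE 0.23), Egr1, a zinc finger factor (1.46, SE 0.21), and Ier2 (0.94, SE 0.06) higher. In knockout cells Ier2 rose by 0.51 (SE 0.10), and Fosb did not pass in edgeR (2.09, SE 0.71, adjusted p = 0.161). Cytosolic ribosomal proteins were listed 42 higher and 2 lower in knockout cells without palmitate (adjusted p = 1.05e-09, 27 called) and 60 and 1 with it (adjusted p = 8.01e-16, 60 called). This group is uncertain, since short members such as Rpl38 (542 bases, 8200 ± 2488) varied widely between untreated knockout libraries, and short genes in general lay at 0.01 in knockout replicate 1 against 0.56 to 0.79 in the others.

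Genes on chromosomes 9 and 14 were mostly lower in knockout cells. In 984 genes chosen on palmitate alone, the median genotype log2 fold change was lower on these chromosomes by 0.102 without palmitate (difference -0.102) and by 0.155 with it (difference -0.155), each with a permutation p of 1e-05, the smallest possible. The chromosomes were picked from these same libraries and genes of 1 chromosome are not independent, so this p is not independent support. Without palmitate the median was -0.012 on chromosome 9 and -0.121 on chromosome 14, against 0.06 elsewhere. With palmitate these medians were -0.112, -0.167 and 0.016. A lower copy number in some of the knockout cells could give such a shift, though the loss of 1 of 4 copies in every cell would give -0.415. Listed genes were matched on GC content and deposited gene length. This left 45.5 percentage points more genes lower on these chromosomes without palmitate (95% range of draws 41.9 to 49.1). With palmitate it left 39.1 (35.8 to 42.2). Before matching the gaps were 47.6 and 41.2, so GC content and deposited length accounted for little of them. Transcript length was not matched, and the genes were chosen for passing in the same comparison, so a transcript length bias was not excluded. Expression alone does not show copy number, and Ripk3 itself lies on chromosome 14.

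The respiratory chain was higher in knockout cells, and so were other short genes. Its median exceeded that of length-matched genes by 0.064 with palmitate (95% range -0.018 to 0.113) and by 0.02 without it (-0.081 to 0.093). A transcript length bias between libraries may therefore account for the size of the shift. It accounts less for the direction. With palmitate 96.8% of the respiratory chain genes were higher, against 74.2% of matched genes (highest draw 88.7%). Without palmitate these shares were 97.5% and 72.5% (highest draw 90%). Among genes with a deposited length of at least 1500 bases 30 were higher and 2 lower with palmitate. That cut need not remove short transcripts, since the listed respiratory chain genes had a median transcript of 786 bases. It therefore does not argue against a transcript length bias. With palmitate all 5 knockout libraries had respiratory chain medians (0.19 to 0.32) above the wild-type range (-0.05 to 0.10). These medians were taken over genes listed for passing in this same comparison, 60 higher and 2 lower, so this outcome was close to fixed in advance. Without palmitate 4 of 5 knockout libraries lay above the wild-type range, over genes chosen the same way. Other short genes moved along, so these medians do not separate a genotype difference from a library effect.

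Fewer genes were listed for palmitate in knockout than in wild-type cells. Among 2239 genes chosen on genotype, edgeR called 466 in wild-type and 230 in knockout cells. Leaving out untreated knockout replicate 4 or 5 raised the latter to 266 and 245, while leaving out replicate 2 or 3 lowered it to 164 each. The median SD of log2 levels was 0.106 in untreated knockout libraries and 0.069 to 0.087 in the wild-type groups, so a wider spread could account for part of the difference. Without untreated knockout replicate 1 the count was 225, whereas leaving out 1 palmitate library lowered it to 155 to 193. Losing a library costs calls by itself, and wild-type libraries were not left out for comparison. The count of 225 therefore does not settle how much replicate 1 contributed. The edgeR test of a different palmitate effect called 0 genes and DESeq2 6, so a smaller effect stays open.

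In each comparison, of 100 drawn splits of the 10 libraries into 5 and 5, only 1, the real one, called as many genes among genes not chosen on that comparison. The real and the highest other split called 466 and 78 genes for palmitate in wild-type cells, 230 and 1 in knockout cells, 271 and 22 for genotype without palmitate, and 394 and 0 with palmitate. For the interaction, where the real grouping called 0, all 100 reassignments of genotype called as many, up to 912, since reassigning carries the genotype difference into the term.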
